A study of Mus musculus with 24 samples.

How the data were processed

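RNA from colon and colorectal tumours of WT and KO mice was extracted with Trizol and made into libraries by standard Illumina methods, per the labels' protocols. Reads were processed with STAR 2.7.6a and RSEM 1.3.1 on GRCm38, per the submitters' processing notes. The annotation release and the strand setting of the libraries are not given in the sources used here. The authors deposited a table per library with RSEM's expected count and TPM for 55487 genes, per the file headers. An expected count is an estimate that shares a read between the genes it fits, and 11.0% to 12.4% of the listed values per library were not whole. TPM as deposited is scaled to the library with RSEM's effective gene lengths and was used only to check Axin1, which in KO was then 29.9% of WT over all libraries, against 31.7% with CPM. Because strand is not given, overlapping and antisense genes cannot be told apart, and members of families with near-identical copies, such as the ribosomal protein copies, the alpha-defensins and the Cyp2c genes, are uncertain. A symbol was found for 55141 of the gene identifiers in a GENCODE table, and the other 346 held at most 0.074% of the counts of a library. Positions are from GENCODE M21 on GRCm38.

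Groups were taken from the labels of genotype, treatment and day, and no library was left without a group. Replicates were numbered only by their order, so the numbers pair no libraries. The design states biological replicates, and no library was a copy of another in its group. Between the replicates of a group the chi-square per gene lay from 16 to 197.8 where sampling noise alone gives about 1. Libraries of different groups were not compared in this way. The groups, the 16 comparisons, the tests, the 34 gene lists, the rule for named genes and the alternatives not said to be added later were chosen before the data were examined.

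Expected counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM normalization, its default filter on low counts (minimum count 10, minimum total 15) and robust estimation, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. Every adjusted p of a gene is from this test unless another tool is named. Colon comparisons used the 18 colon libraries in a single fit of 6 groups (18102 genes), the comparison of tumours between genotypes the 6 tumour libraries (17245 genes), and comparisons between tumours and colon all 24 libraries (19056 genes). Fold changes are on the log2 scale. A fold change of a gene with 0 counts in a group is not given, and in the medians of lists such genes were also set at a lower bound from a floor of 3 counts over the group. CPM levels use the library totals scaled by the normalization factors. Axin1 levels were also compared by an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3 libraries.

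Gene lists cover pathways, cell types of the epithelium, and cells that the tissue can also hold, such as immune cells, muscle, nerves and fibroblasts. They were tested with camera (limma 3.58.1) on voom weights with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. An "adjusted p" printed for a list is from camera. The list of exocrine pancreas genes had too few expressed members and was not tested. Named genes were Axin1, 9 general genes of the question, up to 10 genes per direction with the largest change among those that passed, with a mean of at least 2 CPM in the higher group, no overlap of libraries between groups and no predicted or clone name, and up to 4 members with the smallest p from each list described. With fewer than 5 calls all called genes were taken, and 5 per direction with the smallest p that did not pass. In 3 against 3 libraries chance gives no overlap in 10% of genes. Some genes that met the rule are not reported here. A few genes outside this rule are named as markers of single libraries and were chosen after their values were seen.

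Alternatives were DESeq2 1.42.0 in place of edgeR, other size factors (RLE), no filter and a stricter filter (1 CPM in 6 libraries, or in 3 for tumours), only the groups compared or all libraries in the fit, a covariate of Y-linked expression (prior count 2), the presumed sequencing run as a term, the 4 libraries whose Illumina sample numbers repeat within colon left out, and each library left out in turn. Sample numbers 9 to 16 each occur 2 times among the 24 libraries, so at least 2 runs were presumably pooled. Numbers 9 to 14 are each shared by a colon and a tumour library, and these libraries stayed in. Numbers 15 and 16 are each shared by 2 colon libraries, which are the 4 left out: untreated WT replicate 2, untreated KO replicate 2, WT day 7 replicate 2 and KO day 7 replicate 3. The presumed run term set only WT day 7 replicate 2 and KO day 7 replicate 3 apart from the other colon libraries. That division is a presumption, and the term can adjust the means of the day 7 groups only. Leaving out 3 libraries with outlying marker genes, and a threshold of 0.1 at day 7, were added after the data were seen.

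The method was tested on simulated data with the real means, dispersions and library sizes, in which 50 genes above 1 CPM were changed by each fold. In the day 7 design (17845 genes) 22%, 52%, 86% and 94% of genes changed by 1.5, 2, 4 and 8-fold were called, and 4 of 17645 unchanged genes. In the tumour design (16926 genes) 6%, 42%, 70% and 84% were called, and 9 of 16727 unchanged genes. In all 131 genes were called in the day 7 design and 110 in the tumour design. The adjustment of p is stricter where fewer genes pass, so these shares do not carry over to comparisons with few calls. At depths of 15.65 M to 28.1 M a gene at 1 CPM has few counts per library, so counting error is large below this level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.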

Results

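The series measured messenger RNA in mouse colon and in colorectal tumours, in wild-type (WT) mice and in mice that lack Axin1 in the epithelial cells of the intestine (KO). Axin1 is a scaffold of the complex that marks beta-catenin for destruction, and beta-catenin carries the Wnt signal into the nucleus. Colon was taken from untreated mice and at day 7 and day 13 of an experiment with dextran sulfate sodium (DSS), a polymer in the drinking water that damages the colonic epithelium and causes colitis. Tumours came from mice given azoxymethane (AOM), a carcinogen, together with DSS. Each of the 8 groups held 3 libraries, described as biological replicates, which gave 18 colon and 6 tumour libraries on the C57BL/6 background. Total expected counts ran from 15.65 M to 28.1 M per library, with a median of 23.6 M. Between 22724 and 24648 genes had at least 1 count in a library. The 10 most abundant genes took 5.44% to 12.1% of the counts, and mitochondrial genes took 2.97% to 6.53%. No replicate was a copy of another in its group. Log2 fold changes are given ± SE and levels as counts scaled to library size (CPM), mean ± SD, with n = 3 libraries per group throughout.

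Axin1 (ENSMUSG00000024182, a protein-coding gene on the plus strand of chromosome 17, 26138688 to 26195811 in GRCm38) was measured first, because it checks the genotype labels. Untreated WT colon held 51.8 ± 3.18 CPM and untreated KO colon 17.2 ± 1.72 CPM, which is 33.2% of the WT mean. At day 7 the levels were 50.6 ± 1.61 and 16 ± 0.404 CPM (31.6%), and at day 13 they were 53.5 ± 5.76 and 15.5 ± 2.19 CPM (29.0%). Tumours held 54.9 ± 4.46 CPM in WT and 18.1 ± 1.41 CPM in KO (33.0%). In each of these conditions every KO library lay below every WT library, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. The tissue contains cells other than the epithelium, where the gene was not targeted. The values refer to the whole gene, and the deleted part is not given in the sources used here.

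**Figure D1:**
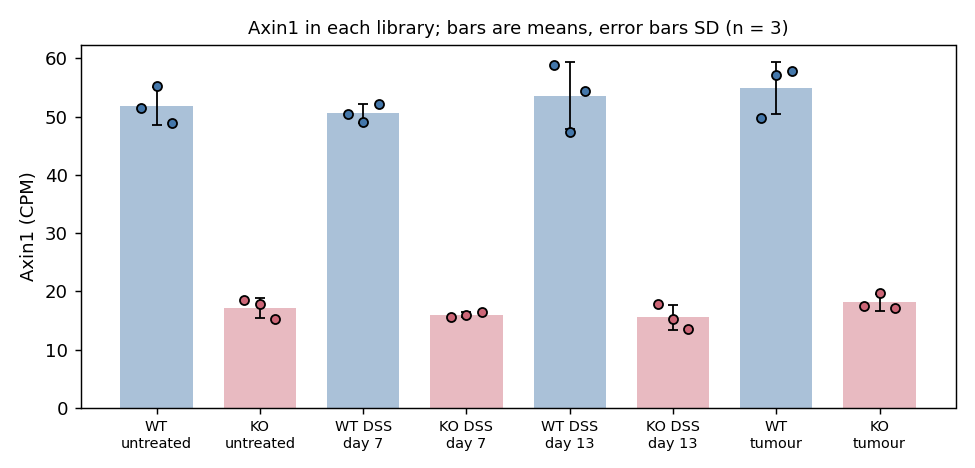
Axin1 level in CPM (vertical axis, from 0) in the 8 groups; bars are means, error bars are SD and points are the 3 libraries of each group. KO means lie between 15.5 and 18.1 CPM and WT means between 50.6 and 54.9 CPM.

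The effect of the missing Axin1 in undamaged colon was asked by comparing untreated KO with untreated WT mice. Apol7a, an apolipoprotein L family gene, was higher in KO by 2.71 ± 0.37 (32.2 ± 19.3 against 4.81 ± 0.440 CPM, adjusted p = 0.023). Axin1 itself fell by 1.62 ± 0.12 (adjusted p = 9.56e-06). Among Wnt genes, Axin2, a direct beta-catenin target that feeds back on the pathway, differed by 0.23 ± 0.18 (adjusted p = 0.817), and Lgr5, a marker of intestinal stem cells, by -0.45 ± 0.68 (adjusted p = 0.91). Differences for Myc (-0.01) and for the cyclin gene Ccnd1 (0.17) also did not pass. The proliferation marker Mki67 differed by -1.08 ± 0.58 (adjusted p = 0.782), the goblet cell mucin gene Muc2 by 1.21 ± 0.65 (adjusted p = 0.784) and the cytokine gene Il1b by 1.32 ± 0.99 (adjusted p = 0.814). Of the genes with the smallest p that did not pass, Zbp1, a sensor of nucleic acids, had 78.3 against 11.8 CPM (2.7 ± 0.52, adjusted p = 0.405), the peptidase gene Enpep 23.4 ± 2.48 against 7.07 ± 1.28 CPM (adjusted p = 0.487), and the aminotransferase gene Kyat1 31.5 against 109.9 CPM (-1.82 ± 0.30, adjusted p = 0.0999).

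Among the gene lists in untreated colon, the 17 genes of the type I interferon response were higher in KO as a set, with a median log2 difference of 2.67 (adjusted p = 4.71e-12; adjusted p = 0.707 with an estimated correlation). None of these genes passed over all genes, and 16 passed when adjusted over the list alone. KO replicate 3 stood apart here, with 126.3 CPM of Isg15 and 597.4 CPM of Irf7, both induced by interferon, and without it the median was 0.91. For the 18 genes of the interferon-gamma response and MHC class II the median was 1.21, with 10 genes passing when adjusted over the list alone (adjusted p = 4.51e-07; adjusted p = 0.707 with an estimated correlation). Smooth muscle genes were lower as a set, by a median of -0.78 over 10 genes, 2 of them when adjusted over the list alone (adjusted p = 5.21e-06; adjusted p = 0.707 with an estimated correlation). Without KO replicate 3 these 2 lists had medians of 1.1 and -0.69, and 0 genes of either passed by edgeR over the list alone. Wnt target genes had a median of -0.07 over 18 genes (adjusted p = 0.834). In all, 2 of 18102 genes passed by edgeR, 1182 had an unadjusted p under 0.05, and DESeq2 called 65. Without KO replicate 2 edgeR called 21. The Apol7a call ended without WT replicate 1, 2 or 3 (adjusted p = 0.349, 0.139 and 0.29, and 1 gene called each time), within a range of 7.58e-10 to 0.395 over its alternatives.

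At day 7 of the DSS experiment the comparison of KO with WT asked whether the missing Axin1 changes the tissue during acute damage. Only Axin1 passed, lower by -1.62 ± 0.12 (adjusted p = 9.37e-06). Axin2 had 36.9 ± 3.51 CPM in KO and 18.3 ± 2.40 CPM in WT (1.04 ± 0.18, adjusted p = 0.0647), and Hes1, a target of Notch signalling, differed by 0.69 ± 0.13 (adjusted p = 0.0647). Inflammatory genes had lower means in KO and did not pass: Il1b had 2.27 ± 0.890 against 28.5 ± 21.9 CPM (-3.61 ± 0.80, adjusted p = 0.0647), and S100a8, a calcium-binding protein gene of neutrophils, 0.334 ± 0.227 against 20.1 ± 18.7 CPM (-5.87 ± 1.22, adjusted p = 0.0647). Il6 had -3.12 ± 0.90 (adjusted p = 0.0691). The myeloid genes Tyrobp (3.09 against 11 CPM) and Aif1 (1.61 against 6.39 CPM) and Gcnt2, a glycosyltransferase gene (21.2 against 64.3 CPM), each had an adjusted p of 0.0647. Lgr5 (1.02, adjusted p = 0.387), Myc (0.03, adjusted p = 0.946), Ccnd1 (-0.20, adjusted p = 0.577), Mki67 (1.23 ± 0.58, adjusted p = 0.187) and Muc2 (-0.77, adjusted p = 0.463) did not pass.

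The lists at day 7 were tested as sets. Of 20 cytokine and chemokine genes none passed over all genes and 17 were lower when adjusted over the list alone, with a median of -2.86 (adjusted p = 1.35e-07; adjusted p = 0.264 with an estimated correlation). Neutrophil genes had a median of -4.03, with 10 of 12 lower when adjusted over the list alone (adjusted p = 8.92e-05; adjusted p = 0.33 with an estimated correlation). For monocyte and macrophage genes the median was -1.17, with 13 of 14 lower in that way, among them the complement gene C1qa (-1.19 ± 0.28) and the Fc receptor gene Fcgr1 (-1.95 ± 0.47; list adjusted p = 6.05e-08; adjusted p = 0.264 with an estimated correlation). T cell genes (11 of 13, median -1.72, adjusted p = 2.66e-06; adjusted p = 0.297 with an estimated correlation) and fibroblast and matrix genes (13 of 14, median -1.23, adjusted p = 1.35e-07; adjusted p = 0.264 with an estimated correlation) were also lower as sets. Enteric neuron and glia genes, which mark the gut wall below the epithelium, were lower in 11 of 11 (median -1.61, adjusted p = 1.35e-07; adjusted p = 0.264 with an estimated correlation). WT replicate 2 held 3411 CPM of the smooth muscle gene Myh11, and without it the medians were -0.80 for enteric neuron and -0.66 for fibroblast genes, with 2 of each list lower over the list alone. They were then -2.19 for cytokine genes (4 lower), -2.61 for neutrophil genes (8), -0.98 for macrophage genes (8) and -1.25 for T cell genes (0). Ribosome biogenesis genes were higher in 10 of 18 when adjusted over the list alone (median 0.37, adjusted p = 1.35e-07; adjusted p = 0.264 with an estimated correlation), and cell cycle genes in 4 of 21 (median 0.73, adjusted p = 3.1e-07; adjusted p = 0.264 with an estimated correlation). Without WT replicate 2 cell cycle genes had 0 over the list alone. The edgeR count was 1 gene of 18102, with 4887 at an unadjusted p under 0.05 and 2453 by DESeq2, so the count depended on the threshold. It was 927 without WT replicate 1 and 2441 without WT replicate 3.

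By day 13 KO colon differed from WT colon in 455 genes, 118 higher and 337 lower. Inflammatory mediators were lower in KO: Il1b had 0.706 ± 0.305 CPM in KO and 53.4 ± 45.9 CPM in WT (-6.23 ± 0.93, adjusted p = 0.00835), the neutrophil chemokine gene Cxcl2 had 0.218 ± 0.231 and 26.4 ± 30.4 CPM (-6.93 ± 1.3, adjusted p = 0.0171), and Acod1, which makes itaconate in activated macrophages, had 0.186 and 31.7 ± 35.3 CPM (-7.42 ± 1.34, adjusted p = 0.0152). S100a8 fell by 5.57 ± 1.13 (1.17 ± 1.80 against 54.6 ± 40.6 CPM, adjusted p = 0.0207) and Il6 by 4.84 ± 1.01 (adjusted p = 0.0226). Among the genes higher in KO, Slc11a2, the divalent metal transporter that takes up iron, had 219.7 ± 100.5 against 54.7 ± 5.78 CPM (2.01 ± 0.40, adjusted p = 0.0201), S100g, a calcium-binding protein of absorptive cells, 173.8 ± 57.4 against 5.50 ± 2.79 CPM (4.99 ± 1.15, adjusted p = 0.0348), and Slc30a10, a manganese transporter, 59.8 against 3.23 CPM (4.22 ± 0.87, adjusted p = 0.0217). The list of absorptive colonocyte genes had 0 of 17 passing by edgeR over all genes or over the list alone (median 0.32, adjusted p = 0.0704). Igsf23, an immunoglobulin superfamily gene, rose by 2.44 ± 0.36 (adjusted p = 0.00835). Axin1 fell by 1.78 ± 0.12 (adjusted p = 2.74e-06). Axin2 had 26.7 ± 4.74 against 17.1 ± 4.10 CPM and did not pass (0.66 ± 0.18, adjusted p = 0.0656), nor did Ccnd1 (-0.76 ± 0.22, adjusted p = 0.0864), Lgr5 (0.72 ± 0.70, adjusted p = 0.638), Myc (-0.11), Mki67 (-0.13) or Muc2 (-0.93 ± 0.65, adjusted p = 0.487).

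**Figure D2:**
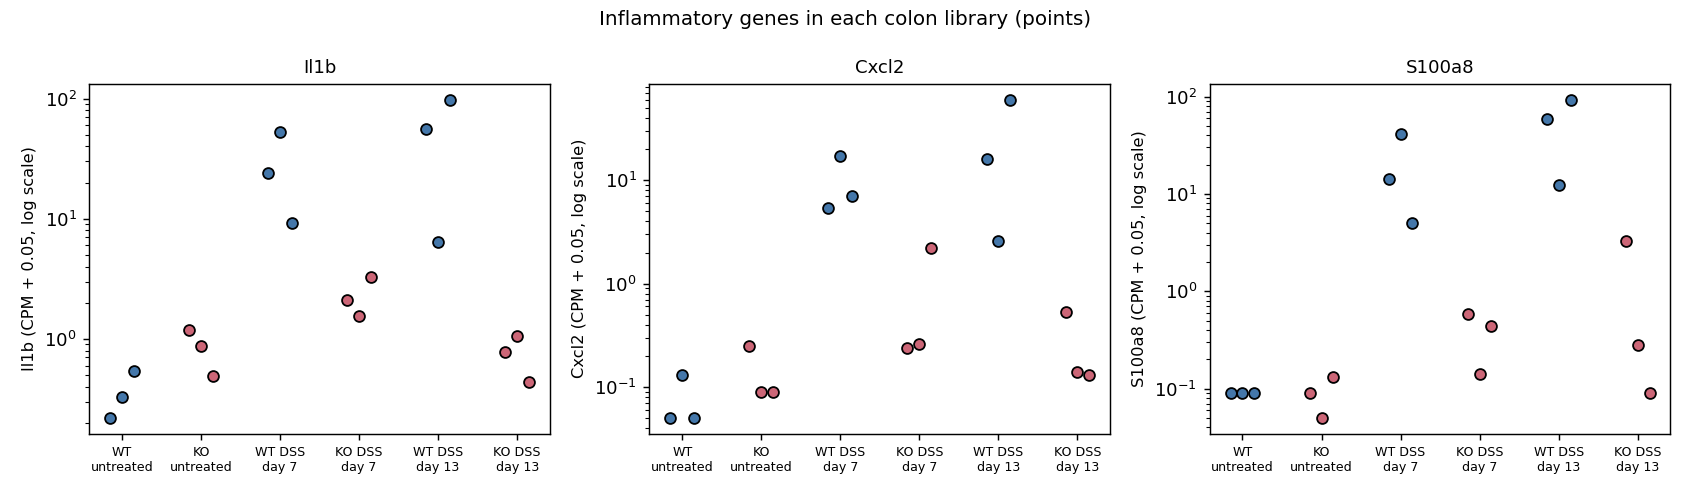
Levels of Il1b, Cxcl2 and S100a8 (vertical axes, CPM + 0.05 on a log scale) in each of the 18 colon libraries, grouped by genotype and day; points are libraries. At day 13 every WT library lies above every KO library for each of the 3 genes.

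Grouped by list, 11 of 20 cytokine and chemokine genes fell at day 13 over all genes tested and 18 when adjusted over the list alone, with a median of -4.23 (adjusted p = 4.83e-12; adjusted p = 0.397 with an estimated correlation). They included Ccl2, which attracts monocytes (-5.07 ± 0.80, adjusted p = 0.0107), and Il11 (-4.77 ± 0.95, adjusted p = 0.0201). Neutrophil genes fell in 9 of 12, and in 9 when adjusted over the list alone, among them Trem1 (-4.98 ± 0.93) and the G-CSF receptor gene Csf3r (-4.74 ± 0.90), with a median of -5.21 (adjusted p = 8.55e-07; adjusted p = 0.4 with an estimated correlation). Monocyte and macrophage genes fell in 10 of 14, and in 14 when adjusted over the list alone, among them Fcgr1 (-3.58 ± 0.51), C1qa (-1.75 ± 0.29) and Adgre1, which encodes F4/80 (-2.18 ± 0.36), with a median of -1.82 (adjusted p = 2.17e-15; adjusted p = 0.362 with an estimated correlation). Of 14 fibroblast and matrix genes 4 fell over all genes and 9 over the list alone, among them the collagen gene Col1a1 (-1.86 ± 0.39, adjusted p = 0.023), with a list median of -1.39 (adjusted p = 1.38e-07; adjusted p = 0.405 with an estimated correlation). Epithelial antimicrobial and acute phase genes fell in 3 of 13, and 5 over the list alone, with Lcn2, which binds bacterial siderophores, at -3.8 ± 0.73 (adjusted p = 0.0175; list median -1.84, adjusted p = 0.0175; adjusted p = 0.4 with an estimated correlation). In the Wnt target list Rnf43, a ligase that removes Wnt receptors, rose by 1.13 ± 0.19 (adjusted p = 0.0111) and was the only one of 18 to pass over all genes, while 2 were higher and 4 lower over the list alone (median -0.20, adjusted p = 0.476; adjusted p = 0.777 with an estimated correlation).

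The day 13 groups also differed in the sex of the mice as read from expression. All 3 WT libraries had the Y-linked gene Ddx3y at 31 to 38.1 CPM, and all 3 KO libraries had Xist, which is expressed from the inactive X chromosome, at 591.2 to 1100 CPM with Ddx3y at 0.05 CPM or less. The labels give no sex. Squamous epithelium markers stood out in WT replicate 3 (Krt14 at 1099 CPM) and in KO replicate 1 (406.5 CPM). With edgeR, 3291 genes had an unadjusted p under 0.05, and DESeq2 called 1337. A covariate of Y-linked expression left 1 gene, and leaving out these 2 libraries together with untreated KO replicate 3, a choice made after the data were seen, left 9. The count was 1, 1380 and 84 without WT replicate 1, 2 and 3, and 14, 117 and 7 without KO replicate 1, 2 and 3. Axin1 passed in each of its 15 alternatives. The Il1b call ended without WT replicate 1 (adjusted p = 0.0523), KO replicate 1 (0.0529) or KO replicate 3 (0.0545), within 5.68e-13 to 0.133 over its alternatives. That of Igsf23 ended without WT replicate 1 (0.0555), within 8.72e-09 to 0.148. Without WT replicate 1, WT replicate 3 and KO replicate 3 in turn, the adjusted p was 0.0555, 0.0558 and 0.0889 for Cxcl2, 0.0722, 0.0767 and 0.0885 for S100a8, 0.0968, 0.0626 and 0.116 for Il6, 0.0911, 0.0866 and 0.0794 for Slc11a2, 0.109, 0.144 and 0.105 for S100g, and 0.0927, 0.0634 and 0.0888 for Slc30a10. It was 0.0555 and 0.0834 for Acod1 without WT replicate 1 and KO replicate 3. KO replicate 1 also ended the calls of Cxcl2 (0.0809), Il6 (0.107), Slc11a2 (0.0996), S100g (0.104) and Acod1 (0.0843). KO replicate 2 did so for Cxcl2 (0.0771), S100a8 (0.0852), Il6 (0.0814), S100g (0.0765), Slc30a10 (0.0765) and Acod1 (0.0623), and WT replicate 2 for S100g (0.052). Over all alternatives the adjusted p reached 0.218 for Cxcl2, 0.497 for S100a8, 0.374 for Il6, 0.365 for Slc11a2, 0.22 for S100g, 0.272 for Slc30a10 and 0.273 for Acod1.

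Averaged over untreated colon, day 7 and day 13, KO differed from WT in 877 genes, 174 higher and 703 lower. Axin2 rose by 0.64 ± 0.10 (adjusted p = 0.0106), Rnf43 by 0.63 ± 0.11 (adjusted p = 0.011) and Slc11a2 by 1.55 ± 0.23 (adjusted p = 0.0101). Il1b fell by 2.84 ± 0.53 (adjusted p = 0.0136), the myeloid receptor gene Clec5a by 2.27 ± 0.35 (adjusted p = 0.0101), the ceruloplasmin gene Cp by 1.98 ± 0.30 (adjusted p = 0.0101), the chemokine receptor gene Ccr1 by 1.49 ± 0.25 and the endothelial adhesion gene Vcam1 by 1.49 ± 0.30 (adjusted p = 0.0164). Dkk2, a secreted Wnt modulator, fell by 1.20 ± 0.27 (adjusted p = 0.0279), and Axin1 by 1.67 ± 0.07 (adjusted p = 2.23e-09). Il6 (-2.94, adjusted p = 0.0754), S100a8 (-3.85, adjusted p = 0.146), Lgr5 (0.43, adjusted p = 0.54), Myc (-0.03), Ccnd1 (-0.27, adjusted p = 0.209), Mki67 (0.01) and Muc2 (-0.17) did not pass. Monocyte and macrophage genes fell in 11 of 14, and in 13 over the list alone, with a median of -1.13 (adjusted p = 7.79e-14; adjusted p = 0.45 with an estimated correlation). Fibroblast and matrix genes also fell in 11 of 14 and in 13 over the list alone, Col1a1 by 1.22 ± 0.22 (list adjusted p = 1.54e-11; adjusted p = 0.45 with an estimated correlation). Fatty acid oxidation genes rose in 2 of 15, while 8 were higher and 1 lower over the list alone, among them Ehhadh (0.58 ± 0.13, adjusted p = 0.0269) and Acadvl (0.39 ± 0.10, adjusted p = 0.0456; list adjusted p = 0.000137; adjusted p = 0.515 with an estimated correlation). With edgeR 4622 genes had an unadjusted p under 0.05 and DESeq2 called 2467.

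For this average, leaving out the 4 libraries whose Illumina sample numbers repeat within colon left 2 genes, of which Axin1 was 1. The fold changes of Axin2 (0.58 ± 0.13), Slc11a2 (1.63 ± 0.28), Clec5a (-1.92 ± 0.40), Cp (-1.7 ± 0.30) and Ccr1 (-1.41 ± 0.30) were then near those with all libraries, but their calls ended (adjusted p = 0.129 each). Those of Il1b (-2.72 ± 0.66, adjusted p = 0.139) and Vcam1 (-1.37 ± 0.33, adjusted p = 0.14) ended as well. For Axin2 the adjusted p lay within 1.49e-06 to 0.129 over its alternatives. The count was 528 with a Y-linked covariate, 530 with no filter on low counts and 169 without the 3 libraries that stood apart, and all 6 day 13 libraries in this average had a sex that coincided with genotype. Single libraries moved the count by over 1.5 times as follows. At day 13 it was 507, 2011 and 252 without WT replicate 1, 2 and 3, and 303, 446 and 236 without KO replicate 1, 2 and 3. At day 7 it was 489 and 2248 without WT replicate 2 and 3, 1426 without WT replicate 1, and 221, 411 and 302 without KO replicate 1, 2 and 3. In untreated colon it was 345, 377 and 369 without WT replicate 1, 2 and 3, and 295 and 481 without KO replicate 1 and 2. The Il1b call ended without untreated WT replicate 3 (adjusted p = 0.0509, within 1.52e-07 to 0.139).

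**Figure D3:**
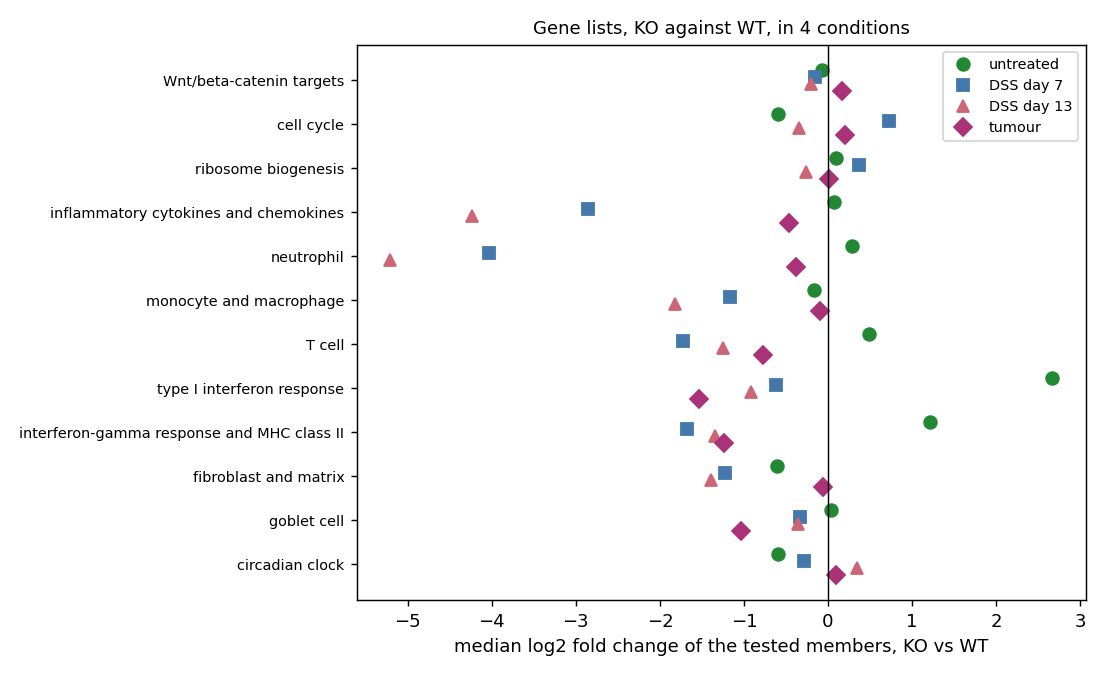
Median log2 fold change of the tested members of 12 gene lists (horizontal axis), KO against WT, in untreated colon, at DSS day 7 and day 13 and in tumours; each point is a list in a condition. The medians of the cytokine, neutrophil and macrophage lists lie at -2.86, -4.03 and -1.17 at day 7 and at -4.23, -5.21 and -1.82 at day 13.

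The response to DSS was measured within each genotype. In WT colon 2949 genes differed between day 7 and untreated mice, 1543 higher and 1406 lower. Clca4b, a chloride channel regulator gene, rose from 5.51 ± 1.60 to 2574 ± 726.6 CPM (8.81 ± 1.39, adjusted p = 0.00175). Il1b rose from 0.313 ± 0.161 to 28.5 ± 21.9 CPM (6.43 ± 0.97, adjusted p = 0.00148), S100a8 from 0.0424 ± 0.00258 to 20.1 ± 18.7 CPM (adjusted p = 0.00282), and Il6 by 5.37 ± 1.11 (adjusted p = 0.00607). Myc rose by 1.43 ± 0.26 (adjusted p = 0.0034) and Ccnd1 by 1.29 ± 0.22 (adjusted p = 0.00247). The fructose transporter gene Slc2a5 fell by 3.41 ± 0.59 (adjusted p = 0.00244) and the clock output gene Dbp by 3.38 ± 0.66 (224.3 ± 21.0 to 22.4 ± 21.9 CPM, adjusted p = 0.00472). Lgr5 fell from 8.36 to 1.16 CPM (-2.85 ± 0.75, adjusted p = 0.0201) and Axin2 by 0.59 ± 0.18 (adjusted p = 0.0351), and these 2 calls were less stable. Lgr5 ended without untreated replicate 1 or 3 (adjusted p = 0.0503 and 0.0657) or day 7 replicate 2 or 3 (0.0519 and 0.0615), within 0.000856 to 0.0989 over its alternatives. Axin2 ended without untreated replicate 1, 2 or 3 (0.0667, 0.0648 and 0.118) or day 7 replicate 1 or 2 (0.0814 and 0.104), within 0.022 to 0.202. The Il6 call held in 10 of 12 alternatives (adjusted p up to 0.0608) and the Dbp call in 13 of 14 (up to 0.053). Mki67 (-0.43, adjusted p = 0.635) and Muc2 (1.25, adjusted p = 0.198) did not pass.

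By list, 16 of 20 cytokine and chemokine genes rose in WT colon at day 7 and 18 when adjusted over the list alone, among them Tnf (4.49 ± 0.72, adjusted p = 0.00184) and Cxcl1 (5.68 ± 0.94, adjusted p = 0.002). Their median was 5.38, or 4.59 with members at 0 in untreated colon set at a bound (adjusted p = 2.64e-06; adjusted p = 0.687 with an estimated correlation). Neutrophil genes rose in 11 of 12, and in 11 over the list alone (adjusted p = 0.00016; adjusted p = 0.687 with an estimated correlation). Antimicrobial and acute phase genes rose in 6 of 13, and in 10 over the list alone, among them Duoxa2, a maturation factor of the epithelial oxidase Duox2 (3.93 ± 0.55, adjusted p = 0.00103), and Duox2 itself (3.62 ± 0.58, adjusted p = 0.00178; list adjusted p = 0.000413; adjusted p = 0.166 with an estimated correlation). Ribosome biogenesis genes rose in 15 of 18, and in 16 over the list alone, among them Rrs1 (1.28 ± 0.15, adjusted p = 0.00064) and Nop56 (1.19 ± 0.17; list adjusted p = 4.13e-14; adjusted p = 0.166 with an estimated correlation). Clock genes fell in 8 of 15, while 10 were lower and 1 higher over the list alone, among them Ciart (-2.61 ± 0.44, adjusted p = 0.00207) and Per3 (-2.18 ± 0.40; list adjusted p = 2.39e-05; adjusted p = 0.166 with an estimated correlation). The labels give no time of day. The 3 WT libraries at day 7 came from female mice by Xist, against 1 of the 3 untreated ones, and the count was 880 with a Y-linked covariate and 1090 without the 4 libraries whose sample numbers repeat within colon. With edgeR 5927 genes had an unadjusted p under 0.05 and DESeq2 called 4071. The count was 1369, 1669 and 1848 without untreated replicate 1, 2 and 3.

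In KO colon 2288 genes differed between day 7 and untreated mice, 1552 higher and 736 lower. Lrp8, a lipoprotein receptor gene, rose from 3.51 ± 1.38 to 27.4 ± 10.2 CPM (2.97 ± 0.32, adjusted p = 0.000126), the secreted phospholipase gene Pla2g2a by 4.80 ± 0.97 (adjusted p = 0.00475), the keratin gene Krt36 by 4.15 ± 0.60 (adjusted p = 0.000516) and Lbp, which binds bacterial lipopolysaccharide, by 3.21 ± 0.61 (adjusted p = 0.00329). Myc rose by 1.48 ± 0.26 (adjusted p = 0.00225). Ccnd1 rose by 0.92 ± 0.22 (adjusted p = 0.0146) and Mki67 by 1.89 ± 0.59 (adjusted p = 0.0499). Il1b (1.5 ± 0.83, adjusted p = 0.27), S100a8 (2.90, adjusted p = 0.375), Il6 (3.12, adjusted p = 0.179), Axin2 (0.22, adjusted p = 0.457), Lgr5 (-1.38, adjusted p = 0.227) and Muc2 (-0.73) did not pass.

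Cell cycle genes rose in 15 of 21 in KO colon at day 7 and in 19 over the list alone, among them the ribonucleotide reductase gene Rrm2 (2.46 ± 0.29, adjusted p = 0.000177) and the replication helicase gene Mcm3 (1.78 ± 0.22, adjusted p = 0.000225), with a list median of 1.76 (adjusted p = 2.93e-18; adjusted p = 0.103 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 18, over all genes and over the list alone, with Nop56 at 1.59 ± 0.17 (adjusted p = 0.000126) and a median of 1.13 (adjusted p = 6.75e-23; adjusted p = 0.103 with an estimated correlation). Clock genes fell in 7 of 15, and in 7 over the list alone, among them Cry2 (-1.5 ± 0.33, adjusted p = 0.00765) and Dbp (-2.22 ± 0.63, adjusted p = 0.0321; list adjusted p = 0.00629; adjusted p = 0.489 with an estimated correlation). Of 20 cytokine and chemokine genes only Cxcl1 rose over all genes (3.02 ± 0.86, adjusted p = 0.0327) and none over the list alone (list median 1.56, adjusted p = 0.274). The Cxcl1 call ended without untreated replicate 2 or 3 (adjusted p = 0.0986 and 0.0994) or day 7 replicate 3 (0.231), within 0.00179 to 0.403. Neutrophil genes had 0 of 12 passing by edgeR (median 1.12, adjusted p = 0.443). Over all genes 4849 had an unadjusted p under 0.05, and DESeq2 called 3159. All 3 untreated KO libraries and 1 of 3 at day 7 had Y-linked expression, and the edgeR count was 1107 with a Y-linked covariate and 949 without the 4 libraries whose sample numbers repeat within colon. The edgeR count was 1426 without untreated replicate 1, and 1350, 1512 and 1278 without day 7 replicate 1, 2 and 3. The Ccnd1 call ended without untreated replicate 1 (adjusted p = 0.0693) or day 7 replicate 3 (0.0687), within 0.00167 to 0.116. For Mki67 the call ended without untreated replicate 1 or 2 (0.148 and 0.154) or day 7 replicate 1, 2 or 3 (0.131, 0.121 and 0.0636), within 0.00153 to 0.169.

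WT and KO shared 730 genes that rose at day 7, where independent lists of 1543 and 1552 would share 132.3 of 18102, and 349 that fell, where 57.2 would be shared. These 2 comparisons have no control library in common, but they come from 1 fit with a shared estimate of the spread. Libraries with Y-linked expression also became fewer from untreated to day 7 in both genotypes, from 2 to 0 in WT and from 3 to 1 in KO. The excess can therefore not be credited to DSS alone. Whether the response itself differed between genotypes was tested as an interaction, and no gene passed by edgeR, while 2487 had an unadjusted p under 0.05 and DESeq2 called 363. Il1b had an interaction of -4.93 ± 1.25 (adjusted p = 0.19), Axin2 of 0.82 ± 0.25 (adjusted p = 0.221), Hes1 of 1.06 ± 0.18 (adjusted p = 0.168) and Mki67 of 2.32 (adjusted p = 0.268). As sets, the genes of the interferon-gamma response and MHC class II had a lower change in KO than in WT, with a median interaction of -2.52. Over the list alone 17 of 18 passed and none over all genes (adjusted p = 2.43e-14, or adjusted p = 0.431 with an estimated correlation). Cell cycle genes responded more, by a median of 1.26, with 0 of 21 passing over all genes by edgeR or over the list alone (adjusted p = 1.01e-06; adjusted p = 0.467 with an estimated correlation). Without untreated KO replicate 2 or 3 the number of genes that passed was 36 and 101.

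At day 13, 767 genes differed from untreated colon in WT, 581 higher and 186 lower. Il1b was 7.37 ± 1 higher (53.4 against 0.313 CPM, adjusted p = 0.0048), S100a8 had 54.6 ± 40.6 against 0.0424 CPM (adjusted p = 0.00735) and Il6 was 5.76 ± 1.10 higher (adjusted p = 0.014). The neuronal gene Tmem35a fell by 2.89 ± 0.41 (adjusted p = 0.00556), the collagen gene Col8a2 by 2.99 ± 0.51 (adjusted p = 0.00892) and Slc30a10 by 3.97 ± 0.86 (49.8 to 3.23 CPM, adjusted p = 0.0229). Axin2 fell by 0.66 ± 0.18 (adjusted p = 0.0481). Myc (0.53, adjusted p = 0.252), Ccnd1 (0.58, adjusted p = 0.14), Lgr5 (-1.57, adjusted p = 0.205), Mki67 (-0.55) and Muc2 (0.98, adjusted p = 0.404) did not pass. Cytokine and chemokine genes rose in 16 of 20, and in 18 over the list alone, with a median of 5.47, or 5.04 with members at 0 in untreated colon set at a bound (adjusted p = 1.61e-10; adjusted p = 0.342 with an estimated correlation). Neutrophil genes rose in 11 of 12, and in 11 over the list alone (adjusted p = 6.74e-08; adjusted p = 0.342 with an estimated correlation). Genes of the regenerating, fetal-like epithelium rose in 4 of 13, and in 6 over the list alone, among them Ly6a (2.32 ± 0.34, adjusted p = 0.00669) and Anxa1 (2.04 ± 0.48; list adjusted p = 0.00206; adjusted p = 0.429 with an estimated correlation). Smooth muscle genes fell in 3 of 10, and in 9 over the list alone, among them Actg2 (-1.55 ± 0.31, adjusted p = 0.0175) and Des (-1.25 ± 0.32; list adjusted p = 6.74e-08; adjusted p = 0.342 with an estimated correlation).

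In this WT comparison 4048 genes had an unadjusted p under 0.05 with edgeR and DESeq2 called 1952. The count was 98, 1620 and 406 without day 13 replicate 1, 2 and 3, and 36, 87 and 151 without untreated replicate 1, 2 and 3. The Il1b call held without each library in turn, but ended with only the groups compared (adjusted p = 0.0581) or without the 4 libraries whose sample numbers repeat within colon (0.0522), within 4.72e-17 to 0.0581. Il6 ended without day 13 replicate 1 (adjusted p = 0.0622) or untreated replicate 1, 2 or 3 (0.0712, 0.0665 and 0.0688), within 0.000597 to 0.0712. S100a8 ended without untreated replicate 1 (adjusted p = 0.05, within 2.58e-09 to 0.0532), and Axin2 without day 13 replicate 1 or 3 (0.141 and 0.133) or untreated replicate 1, 2 or 3 (0.115, 0.105 and 0.154), within 0.0162 to 0.154. Slc30a10 ended without day 13 replicate 1 (0.103) or untreated replicate 1 or 3 (0.097 and 0.0733), within 0.000133 to 0.103. Col8a2 ended without untreated replicate 1 (0.05, within 1.33e-06 to 0.0581).

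In KO colon 5 genes differed between day 13 and untreated mice, 4 higher and 1 lower. Zfp264, a zinc finger gene, had 2.27 ± 0.667 CPM at day 13 and 0 counts in untreated KO colon, Adora1, an adenosine receptor gene, had 14.3 ± 3.8 against 1.53 ± 0.501 CPM (3.23 ± 0.48, adjusted p = 0.0327) and the retinol dehydrogenase gene Rdh9 110.7 ± 10 against 29.0 ± 6.50 CPM (1.94 ± 0.28, adjusted p = 0.0327). Il1b (-0.18 ± 0.90, adjusted p = 0.984), S100a8 (4.68, adjusted p = 0.518), Axin2 (-0.24) and Mki67 (0.40) did not pass. Monocyte and macrophage genes had 0 of 14 passing by edgeR over all genes, while 9 were lower and 1 higher over the list alone, with a median of -0.89 (adjusted p = 2.18e-06; adjusted p = 0.842 with an estimated correlation). With edgeR 1380 genes had an unadjusted p under 0.05 and DESeq2 called 121. The 6 libraries split by sex as well, since all 3 untreated KO libraries expressed Ddx3y and no day 13 one did beyond 0.05 CPM. The count was 1 without untreated replicate 1, 2 or 3, 0 without day 13 replicate 2 or 3, and the calls of Zfp264, Adora1 and Rdh9 ended without each of the 6 libraries, with adjusted p up to 0.938 over their alternatives.

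Tested as an interaction, the day 13 response differed between genotypes for 2 genes. Gzmb, the gene of the cytotoxic protease granzyme B, had -8.93 ± 1.3 (adjusted p = 0.0491), and Gm45104, a predicted gene, 4.60 ± 0.67 (adjusted p = 0.0491). Il1b had -7.55 ± 1.31 (adjusted p = 0.0735), Tyrobp -2.52 ± 0.43 (adjusted p = 0.0735), S100a8 -5.45 (adjusted p = 0.561) and Axin2 0.43 (adjusted p = 0.482). Cytokine and chemokine genes responded less in KO as a set, by a median of -4.31 with 13 of 20 passing over the list alone and 0 over all genes by edgeR (adjusted p = 2.91e-06; adjusted p = 0.413 with an estimated correlation). Monocyte and macrophage genes had a median interaction of -1.55. Over the list alone 12 of 14 passed and 0 over all genes (adjusted p = 1.18e-10, or adjusted p = 0.388 with an estimated correlation). In KO most genes of this list were lower at day 13 than in untreated colon, so this was not merely a smaller rise. Smooth muscle genes had a median of 1.32, with 6 of 10 over the list alone (adjusted p = 4.01e-07; adjusted p = 0.413 with an estimated correlation). With edgeR 2448 genes had an unadjusted p under 0.05 and DESeq2 called 577. The count was 410 without WT day 13 replicate 2, 92 without untreated KO replicate 2 and 0 without most other libraries. Both calls ended without WT day 13 replicate 1 or 3, any KO day 13 library, any untreated WT library, or untreated KO replicate 1 or 3, with adjusted p within 2.36e-07 to 0.25 for Gzmb and 1.33e-08 to 0.25 for Gm45104.

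From day 7 to day 13 in WT colon 11 genes changed, 5 higher and 6 lower, all with an adjusted p of 0.0444. Foxa1, a transcription factor gene of the gut epithelium, rose by 0.56 ± 0.09. Dkk2 fell by 3.06 ± 0.48 (3.38 to 0.389 CPM) and the nucleotide metabolism gene Dut by 0.91 ± 0.15. Il1b (0.94, adjusted p = 0.551) and Myc (-0.91, adjusted p = 0.12) did not pass. Ribosome biogenesis genes were lower at day 13 in 15 of 18 over the list alone and in 0 over all genes by edgeR, with a median of -0.49 (adjusted p = 7.53e-14; adjusted p = 0.376 with an estimated correlation). Smooth muscle genes were lower in 10 of 10 over the list alone and 0 over all genes, with a median of -1.32 (adjusted p = 2.1e-10; adjusted p = 0.376 with an estimated correlation). Without WT day 7 replicate 2 this median was -0.66, with 4 lower over the list alone. With edgeR 3060 genes had an unadjusted p under 0.05 and DESeq2 called 751. All day 7 libraries were female and all day 13 ones male by Xist and Ddx3y. The count was 78, 19 and 2 without day 7 replicate 1, 2 and 3, and 0 without day 13 replicate 1, 2 or 3. Each of the named calls ended without day 13 replicate 1, 2 or 3, with adjusted p up to 0.639 over their alternatives.

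In KO colon 2321 genes changed from day 7 to day 13, 763 higher and 1558 lower. Rrm2 fell by 2.44 ± 0.29 (adjusted p = 0.000144), the cell cycle transcription factor gene E2f2 by 2.52 ± 0.43 (55.7 ± 16.6 to 9.70 ± 2.05 CPM, adjusted p = 0.00125), Lrp8 by 2.94 ± 0.32 (adjusted p = 0.000103) and Ccnd1 by 1.27 ± 0.22 (adjusted p = 0.0017). Myc fell by 1.05 ± 0.26 (adjusted p = 0.015). The calcium channel gene Cacna1e rose by 2.62 ± 0.39 (4.07 ± 1.13 to 25.0 ± 1.24 CPM, adjusted p = 0.000474) and Dbp by 2.83 ± 0.65 (22.4 ± 11.3 to 158.3 ± 4.29 CPM, adjusted p = 0.00917). Cell cycle genes fell in 12 of 21, and in 18 over the list alone, with Mcm3 at -2.03 ± 0.22 (adjusted p = 0.000103) and a median of -1.56 (adjusted p = 2.36e-15; adjusted p = 0.131 with an estimated correlation). Ribosome biogenesis genes fell in 17 of 18, and in 18 over the list alone, with Wdr43 at -1.3 ± 0.13 (adjusted p = 9.67e-05; list adjusted p = 1.74e-22; adjusted p = 0.125 with an estimated correlation). Clock genes rose in 8 of 15, and in 10 over the list alone, with Cry2 at 1.75 ± 0.33 (adjusted p = 0.00262; list adjusted p = 2.89e-05; adjusted p = 0.131 with an estimated correlation). With edgeR 4686 genes had an unadjusted p under 0.05 and DESeq2 called 3108. Whether this change differed from that in WT was not tested. The count was 1358 and 1436 without day 13 replicate 1 and 2, and 1517 and 1394 without day 7 replicate 1 and 3. The Myc call ended without day 13 replicate 1 or 2 (adjusted p = 0.0708 and 0.0718) or day 7 replicate 3 (0.0971), within 0.00186 to 0.117, and that of Dbp without day 7 replicate 3 (0.052, within 4.16e-05 to 0.0828).

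In tumours the genotypes were compared to ask whether the missing Axin1 changes tumour tissue. No gene passed by edgeR, 654 of 17245 had an unadjusted p under 0.05, and DESeq2 called 22. Axin1 had -1.60 ± 0.11 (adjusted p = 0.0866). Axin2 had 397.6 ± 38.5 CPM in KO and 327.8 ± 131.9 CPM in WT (0.28 ± 0.32) and Mki67 272.4 ± 37.9 and 197.4 ± 32.6 CPM (0.47 ± 0.17), each with an adjusted p of 0.942. Lgr5 had 88.3 and 89.0 CPM (-0.01 ± 0.21, adjusted p = 0.999). An adjusted p of 0.942 also went with the glutathione peroxidase gene Gpx2 (757.8 ± 46.9 against 1170 ± 54.3 CPM), the haptoglobin gene Hp (40.2 ± 5.81 against 107.6 ± 32.2 CPM) and the mitotic kinesin gene Kif4 (37.4 ± 0.817 against 27.6 ± 1.44 CPM). The same was true of Myc (-0.30), Ccnd1 (-0.42), Il1b (-0.42), S100a8 (-0.62) and Muc2 (-1.95 ± 0.96). Wnt target genes had a median of 0.17 over 20 genes (adjusted p = 0.193). Cell cycle genes were higher in KO as a set, by a median of 0.20 over 21 genes (adjusted p = 4.63e-08; adjusted p = 0.681 with an estimated correlation). Type I interferon genes were lower, by a median of -1.54 over 17 genes (adjusted p = 1.29e-05; adjusted p = 0.681 with an estimated correlation), and none of either list passed over all genes or over the list alone. In simulated data of this design 42% of genes changed by 2-fold and 70% of those changed by 4-fold were called. That simulation had 110 called genes, which makes the Benjamini-Hochberg adjustment more lenient than with 0 called. Its shares therefore do not carry over to this comparison, in which Axin1 itself did not pass.

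Tumours differed from untreated colon in 9291 genes in WT (5252 higher, 4039 lower) and in 9502 in KO (5029 higher, 4473 lower) of 19056. Tumours and colon came from different experiments, so tissue, AOM and DSS exposure and batch are not separated. Axin2 rose by 3.63 ± 0.26 in WT (327.8 ± 131.9 against 26.6 ± 2.96 CPM, adjusted p = 6.51e-08) and by 3.65 ± 0.26 in KO (397.6 ± 38.5 against 31.7 ± 3.57 CPM, adjusted p = 5.26e-08). Lgr5 rose by 3.41 ± 0.60 and 3.82 ± 0.62 (adjusted p = 0.000162 and 7.19e-05), and Myc by 2.30 ± 0.28 and 1.99 ± 0.28 (adjusted p = 5.04e-06 and 2.08e-05). The Wnt inhibitor gene Notum rose by 10.67 ± 0.54 in WT and 10.13 ± 0.51 in KO (adjusted p = 9.47e-10 and 9.94e-10), and Prox1, a transcription factor gene, by 6.28 ± 0.35 and 6.94 ± 0.36. Wnt10a had 39.7 ± 26.3 CPM in WT tumours and 0 counts in untreated WT colon, and 56.1 ± 12.6 CPM in KO tumours against 0.0249 CPM. Mmp7, a matrix protease gene of Paneth cells, rose by 12.30 ± 1.32 in WT (455.3 ± 82.4 against 0.0861 CPM, adjusted p = 1.39e-06) and by 7.56 ± 1 in KO (adjusted p = 1.16e-05). In KO against WT the log2 difference of Mmp7 was 4.16 in untreated colon and -0.55 in tumours. The 2 rises of Mmp7 therefore differ mostly through the untreated level. Mki67 rose in KO by 1.57 ± 0.53 (adjusted p = 0.0202) and did not pass in WT (0.05, adjusted p = 0.946). That KO call of Mki67 ended without untreated replicate 1 or 2 (adjusted p = 0.0867 and 0.089) or tumour replicate 1 (0.0526), within 0.000106 to 0.127. Muc2 fell in KO by 3.20 ± 0.85 (adjusted p = 0.00455) and had -0.02 in WT (adjusted p = 0.986), where tumour replicate 1 held 4282 CPM and its omission gave -1.54 ± 0.79 (adjusted p = 0.117, within 0.117 to 1 over the alternatives). The interaction for Muc2 was -3.18 ± 1.13 (adjusted p = 0.446). Without untreated KO replicate 3, which held 10726 CPM of Muc2, the KO call ended (0.0987, within 5.16e-05 to 0.102).

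**Figure D4:**
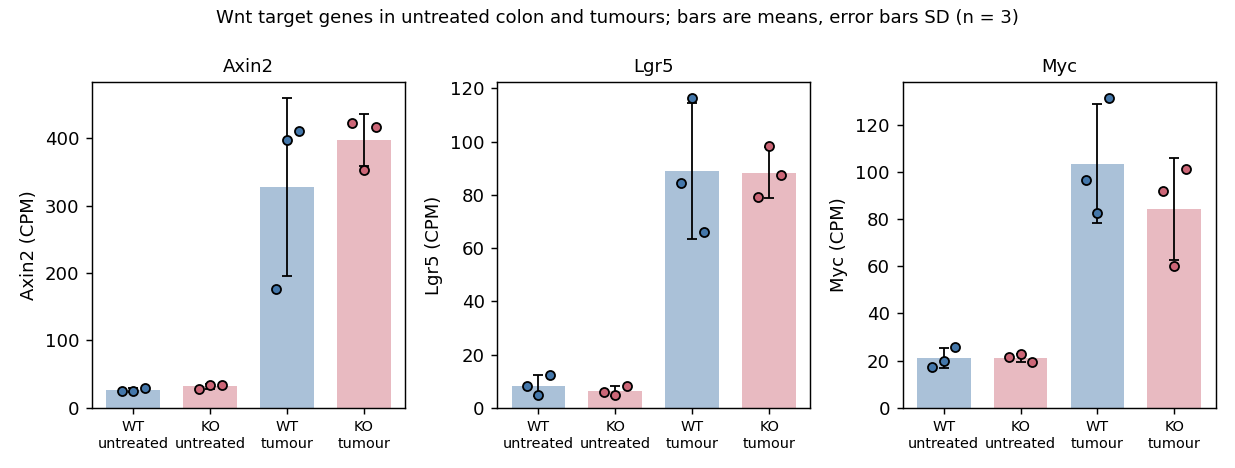
Levels of the Wnt target genes Axin2, Lgr5 and Myc (vertical axes, CPM, from 0) in untreated colon and tumours of WT and KO mice; bars are means, error bars are SD and points are the 3 libraries of each group. Axin2 means are 26.6 and 31.7 CPM in untreated colon and 327.8 and 397.6 CPM in tumours.

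By list, Wnt target genes rose in 20 of 20 in WT tumours and in 20 of 20 in KO tumours, over all genes and over the list alone, with medians of 3.61 and 3.76 (adjusted p = 4.05e-13 and 1.17e-13; adjusted p = 0.149 and 0.147 with an estimated correlation). Deep crypt secretory and Paneth cell genes rose in 7 and 6 of 8, over all genes and over the list alone, among them the lysozyme gene Lyz1 (8.10 ± 0.71 and 7.89 ± 0.70; list adjusted p = 0.000273 and 0.000285; adjusted p = 0.149 and 0.205 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 18 in WT and in KO, over all genes and over the list alone (median 1.14 and 0.99, adjusted p = 3.05e-10 and 1.19e-09; adjusted p = 0.243 and 0.205 with an estimated correlation). Cytokine and chemokine genes rose in 19 and 18 of 20 over all genes and in 19 and 19 over the list alone, with Il1b at 8.18 ± 0.96 and 6.42 ± 0.86 (list adjusted p = 4.6e-05 and 8.48e-05; adjusted p = 0.348 and 0.314 with an estimated correlation). Smooth muscle genes fell in 10 of 10 in WT and in KO, over all genes and over the list alone, among them Actg2 (-6.08 ± 0.42 and -4.71 ± 0.39) and Des (-6.74 ± 0.52 and -5.56 ± 0.49; list adjusted p = 5.86e-11 and 3.93e-09; adjusted p = 0.149 and 0.205 with an estimated correlation). Absorptive colonocyte genes fell in 10 of 17 in WT and 16 of 17 in KO, and in 11 and 16 over the list alone, among them the carbonic anhydrase gene Car4 (-5.56 ± 0.66 and -6.87 ± 0.70; list adjusted p = 0.000124 and 1.13e-05; adjusted p = 0.274 and 0.205 with an estimated correlation). Enteroendocrine genes fell in 11 and 12 of 13, over all genes and over the list alone (median -3.30 and -2.88, adjusted p = 1.62e-05 and 2.84e-05; adjusted p = 0.149 and 0.205 with an estimated correlation).

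The 2 tumour comparisons shared 3964 higher genes, where independent lists would share 1386. They also shared 3199 lower genes, where 948.1 would be shared. They have no control library in common, but come from 1 fit with a shared estimate of the spread. As an interaction, no gene differed between WT and KO in its tumour change by edgeR, 1652 had an unadjusted p under 0.05 and DESeq2 called 91. Axin2 had an interaction of 0.02 ± 0.34 (adjusted p = 0.997), and Wnt target genes a median of 0.04 over 20 genes (adjusted p = 0.564). Zbp1 had -4.18 ± 0.82 and the ubiquitin-like gene Isg15 -6.23 ± 1.29, each with an adjusted p of 0.292, and type I interferon genes a median of -4.18, with 17 of 17 lower over the list alone and 0 over all genes by edgeR (adjusted p = 7.11e-13; adjusted p = 0.587 with an estimated correlation). Without untreated KO replicate 3 this median was -2.19, with 13 lower over the list alone. Without untreated KO replicate 2 or 3 the count was 20 and 14, without WT tumour replicate 2 it was 43, and without KO tumour replicate 1 it was 1. With an estimated correlation none of the 198 calls of the lists held in any of the 16 comparisons.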

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

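The tests of sex at day 13 only, of a lower share of immune cells and of untreated KO replicate 3 were chosen after the results were seen, and the other tests had their predictions written before they were run.

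A test of the difference itself singled out the day 13 interaction between genotype and DSS, in which 2 genes passed. Gzmb had a log2 value of -8.93 ± 1.3. It was at 0.88 to 6.82 CPM in WT at day 13, 0.18 to 0.23 CPM in KO at day 13, 0.3 to 2.92 CPM in untreated KO colon and 0 to 0.09 CPM in untreated WT colon. Gm45104 had 4.6 ± 0.67, with 13.5 to 17.7 CPM in KO at day 13 and 0.76 to 5.46 CPM in untreated colon of either genotype. When genotype labels were drawn within each condition, 2 of 30 draws, the real one among them, had as many genes, and the highest other draw had 91. Labels drawn at random could therefore produce this count.

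Cytokine, neutrophil and macrophage genes were lower in KO than in WT colon at day 13, with a median log2 fold change of -3.74 over 46 genes, 30 of them called, and a median SE of 0.91. With a Y-linked covariate the median was -3.4 and the median SE 1.3, so the fold change stayed while its error grew, and the calls ended with 0 genes. The median stayed beyond -1.87, which is 0.5 of its value and was the limit predicted for a sex effect of the same size at all times. Among colon groups only untreated WT, with 1 female library, and KO at day 7, with 1 male library, held both sexes. These few libraries set the sex estimate, and Il1b was at 3.24 CPM or less in them. The covariate alone can therefore not exclude such a sex effect. At day 7, however, all 3 WT and 2 of 3 KO libraries were female. The cytokine, neutrophil and macrophage lists still had KO against WT medians of -2.86, -4.03 and -1.17. Without WT day 7 replicate 2 they were -2.19, -2.61 and -0.98. A constant effect that lowers these genes in females would not give this. These values argue against it as the only account for these lists, although none of their genes passed over all genes at day 7. Without the 2 day 13 libraries with squamous markers and untreated KO replicate 3 the day 13 median was -3.65. The median SE was 1.04 and 1 gene was called, with fewer libraries left to estimate the error. A sex effect present only at day 13 might give the same values, since all 6 day 13 libraries had a sex that coincided with genotype, and this cannot be told apart from an effect of Axin1.

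A lower share of neutrophils and macrophages in KO tissue stays open as a biological account. Of 26 tested markers of these cells 25 had a negative log2 fold change, but these are the genes of the pattern itself, so the value decides nothing. Lower expression in the same number of cells might give it too.

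Type I interferon genes were higher in untreated KO colon, with a median of 2.67 over 17 genes and a median SE of 0.73. Without KO replicate 3 the median was 0.91, under 1.33, which is 0.5 of the full value, with a median SE of 0.56, and 5 genes passed over the list alone. The size of the difference therefore rested on this library. Leaving out the 4 libraries whose sample numbers repeat within colon gave 3.12 with a median SE of 0.74, but this kept KO replicate 3, which carries the difference, so it says nothing about the presumed sequencing run, and that stays open. A biological cause in this mouse, such as an infection, was not tested and could not be from these data.

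Labels were also exchanged between libraries in the other comparisons. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. As many genes as the real split were called in 1 split for KO against WT in untreated colon (2 genes, highest other 0), at day 7 (1 gene, highest other 0) and at day 13 (455, highest other 2), and in 10 in tumours, where the real count was 0 and the highest other 0. It was 1 split for day 7 against untreated colon in WT (2949, highest other 0) and KO (2288, highest other 0), for day 13 against untreated colon in WT (767, highest other 0) and KO (5, highest other 0), and for day 13 against day 7 in KO (2321, highest other 0). Tumours against colon had 1 in WT (9291, highest other 0) and 1 in KO (9502, highest other 136). For day 13 against day 7 in WT it was 3. The split with the most calls set day 13 replicates 1 and 2 and day 7 replicate 3 against the others. It called 911 genes where the real one called 11. What separates these 2 sets of libraries was not tested.

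For the mean genotype effect over the colon conditions 1 of 30 draws, the real one, had as many genes (877, highest other 1), so labels drawn at random do not account for it. For the interactions at day 7 and in tumours the real count was 0, so 30 of 30 draws had as many, with highest others of 0 and 18.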

How the results depend on the processing

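Leaving out the 3 libraries that stood apart and the threshold of 0.1 were chosen after the data were seen. Axin1 kept its direction and its call in each alternative of the 3 colon comparisons and their mean. Over all named genes 6034 values came from alternatives, of which 5022 stayed on the same side of the threshold, 863 lost the call and 149 gained it. A change of direction was counted only where the gene was called in the main test or in the alternative, and 0 were found. Direction was not counted for genes called in neither. Of 3149 values for called genes 2286 kept the call. No paired analysis was possible because the labels give no replicate numbers. The cause was not tested where counts below moved, other than that fewer libraries were used when some were left out. Where an omission left 2 libraries in a group, edgeR's pooled dispersion was used. Depth limited genes of few counts.

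Counts of called genes moved by over 1.5 times as follows. With DESeq2, KO against WT had 65 genes in untreated colon, 2453 at day 7, 1337 at day 13, 2467 for the mean and 22 in tumours; day 13 against untreated had 1952 in WT and 121 in KO, day 13 against day 7 in WT 751, and the interactions 363 at day 7, 577 at day 13 and 91 in tumours. With the Y-linked covariate KO against WT had 1 gene in untreated colon, 1 at day 13 and 528 for the mean. Day 7 against untreated then had 880 in WT and 1107 in KO, day 13 against untreated 427 in WT and 0 in KO, day 13 against day 7 in WT 0, and the day 13 interaction 0.

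With the 4 libraries whose sample numbers repeat within colon left out, KO against WT had 1 gene in untreated colon and 2 for the mean. Day 7 against untreated had 1090 in WT and 949 in KO, day 13 against untreated in WT 18, day 13 against day 7 0 in WT and 1493 in KO, and the day 13 interaction 0. With no filter on low counts KO against WT had 2 at day 7, 286 at day 13, 530 for the mean and 1 in tumours, day 7 against untreated in KO 1487, day 13 against untreated in WT 508 and day 13 against day 7 in WT 0. The stricter filter gave 28 for day 13 against day 7 in WT. With only the groups compared KO against WT at day 13 had 14, day 7 against untreated 931 in WT and 1510 in KO, day 13 against untreated 57 in WT and 17 in KO, day 13 against day 7 5 in WT and 3603 in KO, and the day 13 interaction 0. With all 24 libraries the mean had 1405 and tumours 1.

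With the presumed run as a term KO against WT at day 7 had 4, day 13 against untreated in KO 3, day 13 against day 7 in WT 0 and the day 13 interaction 0. Without the 3 libraries that stood apart KO against WT had 9 at day 13 and 169 for the mean, day 13 against untreated in KO 1, day 13 against day 7 in WT 0, and the interactions 45 at day 7 and 1 at day 13. A threshold of 0.1 gave 2451 for KO against WT at day 7. With an estimated correlation 0 of the 198 list calls held, and 197 held with RLE size factors. Axin1 in KO at day 7 was 29.8% of WT in TPM as deposited.

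Without each library in turn KO against WT had 1 to 21 genes in untreated colon, 1 to 2441 at day 7, 1 to 1380 at day 13, 221 to 2248 for the mean and 0 in tumours. Day 7 against untreated had 1369 to 2627 in WT and 1278 to 2026 in KO, day 13 against untreated 36 to 1620 in WT and 0 to 4 in KO, and day 13 against day 7 0 to 78 in WT and 1358 to 1733 in KO. The interactions had 0 to 101 at day 7, 0 to 410 at day 13 and 0 to 43 in tumours, and tumours against colon 7868 to 9222 in WT and 7890 to 9087 in KO. Axin1 in KO lay between 31.2% and 32.2% of WT over all libraries.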

Other observations

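The genes in this part were chosen after their values were seen, and the prediction for the neighbours of Axin1 was written before that test.

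Gm44958, a predicted gene on chromosome 6 (131291603 to 131292338), was at 0.64 to 2.28 CPM in all 12 KO libraries and at 0 to 0.1 CPM in all 12 WT libraries. St8sia1, a sialyltransferase gene, lies on the same chromosome (142821545 to 142964452). Its log2 fold changes in KO against WT were -1.19 in untreated colon, -1.34 at day 7, -1.78 at day 13 and -1.05 in tumours. Zfp264 was at 1.5 to 2.72 CPM in the 3 KO libraries of day 13 and at 0.05 CPM or less in every other library. It lies on chromosome 7 (from 6977246), as do Gm45104 (from 18396516) and Igsf23 (from 19937305), which also had higher means in KO at day 13.

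Sequence variants carried along with the targeted Axin1 locus on chromosome 17 could give differences between genotypes in all conditions. A repeated difference was an unadjusted p under 0.05 by edgeR in the same direction in at least 3 of 4 conditions. Among 440 genes within 10 Mb of Axin1, with Axin1 left out, 1 (0.227%) had it, against 131 of 16097 elsewhere (0.814%). The ratio was 0.279 (one-sided Fisher exact p = 0.972), so no excess near Axin1 was found. The genes elsewhere included immune genes lower at day 7, day 13 and in tumours, such as Nos2 (-2.08, -4.18 and -1.44). Such genes raise the share elsewhere, so the ratio is a weak test of linked variants. Variants carried on other chromosomes, such as 6 and 7, were not tested.

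Untreated KO replicate 3 had 12058 CPM of Car1, 10726 CPM of Muc2, 334.7 CPM of Cdx2 and 1292 CPM of Reg3b. Tumour WT replicate 1 had 175.7 CPM of Axin2, against 397.9 and 410 CPM in the other WT tumours, together with 4282 CPM of Muc2 and 78.9 CPM of the albumin gene Alb. KO tumour replicate 1 had 77.2 CPM of Gm45104. The clock gene Dbp was at 200.4 to 239.3 CPM in untreated WT colon and at 92.3 to 125.2 CPM in untreated KO colon. Libraries with Y-linked expression numbered 2 of 3 in untreated WT colon, 3 in untreated KO, 0 and 1 in WT and KO at day 7, 3 and 0 at day 13, and 2 and 2 in tumours.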
